A study of Mus musculus with 34 samples.

How the data were processed

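RNA sequencing was done on 34 mouse libraries of poly-A mRNA, whose groups are listed under Results. The values deposited by the authors are FPKM, fragments scaled to gene length and to the size of the library, with no scaling between libraries stated. The header of 1 of the 5 tables names the unit. For the other 4 it was judged from the values, which were not whole numbers, had unequal library sums and covered the same range as the first table. Reads had been aligned with TopHat2 to mm10 per the submitters' processing notes, which give no TopHat2 version and name no counting tool, annotation or filter.

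Genes were used as listed, with 20458 in the XEN-like table, 48278 in the hepatic table, 43397 and 34932 in the neuronal tables and 48278 in the table of the P24 library. Rows whose identifier occurred more than once were dropped (118 in the hepatic table, 99 in the first neuronal table and 118 in the P24 table), as was 1 row of the XEN-like table with an empty cell. Gene symbols, identifiers and positions came from the GENCODE vM21 annotation of mm10, with positions counted from 1. It matched 97.3% to 99.5% of identifiers per table. All columns of the tables were used.

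Total counts were not stated. The apparent depth was estimated from single-exon genes, in which the smallest values above 0 stand for 1 fragment, by finding the step in the distribution of the depths these values imply. All 34 libraries showed such a step. The estimates reached from 6300000 to 9500000 fragments in the XEN-like table, 6300000 to 10200000 in the hepatic table, 9500000 to 12600000 and 8300000 to 8900000 in the neuronal tables and 11700000 in the P24 library. They depend on gene lengths in the annotation and may be off by a factor of 2, so no floor or interval was computed from them.

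Groups followed the labels. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an alternative is described as added later. Values were taken as log2(FPKM + 1). Genes entered a comparison when they reached 1 FPKM in at least 2 of its libraries. Linear models were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend of the variance on expression. The 16 libraries of the XEN-like table shared 1 model with a term for the flow cell (HJMKLALXX against the HVN codes) that the library titles give, and the value of the lines was the mean of the F25 mean and the s39 mean. Passage number, as given in the titles, was centred within each line and fitted as a slope. The 10 libraries of the hepatic table shared 1 model without such a term, since 1 flow cell held the hepatocytes and tissue and nothing else. TauEGFP colonies and primary neurons were compared with the table as a block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1 in size, and for the passage slope at the adjusted p alone. The p-values measure the spread between libraries of a group, which may be technical repeats of a culture or samplings of a line at other passages, and the labels do not say which libraries share an animal. All tests were two-sided.

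Gene lists were tested with camera on the same models, with a preset correlation between genes of 0.01 and, as an alternative, a correlation estimated for each list. Lists with at least 5 genes in a comparison were tested, and p-values were adjusted over the lists of the comparison. Counts given as adjusted over the list alone use the Benjamini-Hochberg method within the list. Neuronal libraries without replicates were described by log2 differences within their table, and each list median was set against 10000 random lists matched in size and expression.

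Genes were named by a rule. It took the 8 largest differences in each direction among called genes whose groups did not overlap and whose mean in the higher group was at least 10 FPKM, without unnamed gene models. It also allowed up to 4 called members of a list, those with the largest differences, and uncalled members. Which of these were printed as examples was chosen after their values were seen, and so were the few genes described that way in the text. A few genes are not reported here and were left out of the search for libraries far from their group, while the list tests include them.

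The models were tested on simulated data of the same size, with 50 genes changed at each log2 size and the spread taken from the real libraries. At sizes of 1.5, 2, 4 and 6 the share recovered was 64%, 76%, 100% and 96% for colonies against fibroblasts, 50%, 72%, 100% and 100% for lines against fibroblasts, and 74%, 86%, 98% and 100% for lines against colonies. For the passage slope it was 62%, 62%, 92% and 100%. For hepatocyte-like cells it was 16%, 34%, 92% and 94% against fibroblasts, 36%, 60%, 94% and 94% against hepatocytes, and 26%, 42%, 96% and 98% against tissue. For hepatocytes against tissue it was 10%, 40%, 74% and 96%, and for TauEGFP colonies against primary neurons 0% at every size. Unchanged genes that were called numbered 0 to 12 per comparison. A simulated changed list passed and 0 of 20 random lists passed in each of the 9 comparisons, and with an estimated correlation the changed list passed in all but TauEGFP colonies against primary neurons (adjusted p = 0.844). Genes were simulated independently of each other, so the passing of no random list does not show that the preset correlation holds for the real libraries.

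Alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling of the libraries, no flow cell term, single flow cells, a replicate block, no trend of the variance, only the groups compared, and leaving out each replicate in turn. A method for counts was not run, since the values are not counts. Because numbers in the labels might pair libraries, the correlation across genes of the difference between replicates 1 and 2 in 1 group with that in the other was checked. It was 0.036 for fibroblasts and colonies, -0.102 for TauEGFP colonies and primary neurons, and -0.751 for hepatocytes and tissue, whose numbers only follow the order of listing. Repeated libraries were looked for among 42 pairs within groups. The most alike, the s39 pair, had an SD of the log2 ratio of 0.244 over well expressed genes, and no pair had more than 1 identical value above 0. Tests and log2 differences were taken within a table. Values were set side by side across tables for the P24 library, which has no other library in its table, and for the content of the library labelled primary neurons 2. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.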

Results

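Gene expression was measured by RNA sequencing in 34 mouse libraries from a study that turned fibroblasts, with chemicals, into cells resembling extraembryonic endoderm (XEN-like cells) and from there into neuronal and hepatocyte-like cells. The table on the XEN-like state held 16 libraries, with 2 of fibroblasts, 8 of XEN-like colonies, 3 of the XEN-like line F25, 2 of the line s39 and 1 of XEN cells labelled as chemically derived eXEN. The hepatic table held 10 libraries, with 4 of hepatocyte-like cells derived from XEN-like cells, 2 of hepatocytes, 2 of hepatic tissue and 2 of fibroblasts. The neuronal tables held 8 libraries in all, with 2 of colonies marked by a Tau-EGFP reporter (TauEGFP colonies), 2 of primary neurons, and 1 each of fibroblasts, brain, neuronal cells induced directly by the chemical mixture FICB, and a culture labelled P24 XEN-derived neurons. Values were in FPKM, so total counts were not known. The apparent depth, estimated from the spacing of the lowest values, lay between 6300000 and 12600000 fragments per library and may be off by a factor of 2. Between 10312 and 14466 genes per library reached 1 FPKM.

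The first comparison asked how the XEN-like colonies differed from fibroblasts, the cell type they were made from. The labels tie no colony to either fibroblast library. The colonies held high levels of endoderm regulators and epithelial keratins that were near 0 in fibroblasts. Sox17, an endoderm transcription factor (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354), was at 548 ± 345 FPKM (SD, n = 8) against 0.142 ± 0.0580 (SD, n = 2) in fibroblasts, a log2 difference of 8.84 ± 0.30 (SE) with an adjusted p of 3.98e-11. Gata4, another regulator of extraembryonic endoderm (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692), was at 315 ± 93.2 against 0.605 ± 0.564 (log2 difference 7.69 ± 0.21, adjusted p = 5.87e-12). The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) was at 0.984 ± 0.351 in colonies against 6754 ± 2819 in fibroblasts (log2 difference -11.68 ± 0.33, adjusted p = 5.87e-12). The matrix protease Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975) was at 0.201 ± 0.165 against 814 ± 265 (log2 difference -9.41 ± 0.24, adjusted p = 5.21e-12). Each of these 4 genes had the same direction in all 8 colonies, which the naming rule required of them.

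Of the 16 core genes of extraembryonic endoderm, 14 were higher in colonies and none lower (14 also when adjusted over the list alone; median log2 difference 5.40; list test adjusted p = 2.79e-11, adjusted p = 0.0697 with an estimated correlation). Among them the keratins Krt8 and Krt18, which form the filaments of simple epithelia, were at 803 ± 278 and 982 ± 388 FPKM. In the 2 fibroblast libraries Krt8 reached at most 1.32 and Krt18 lay at 1.53 ± 0.689. Gata6 and Sox7, members that were chosen after their values were seen because they are textbook markers of this lineage, were at 42.6 ± 23.8 and 68.6 ± 32.6 against 2.89 ± 1.31 and 1.16 ± 1.28. Dab2, an endocytic adaptor, did not pass the test, with 40.9 ± 23.9 against 45.8 ± 40.1. Of 13 visceral endoderm genes that passed the filter, 7 were higher and none lower (7 adjusted over the list alone, adjusted p = 0.00481, adjusted p = 0.212 with an estimated correlation). Examples were the signal Ihh at 81.3 ± 37.4 against 0.117 ± 0.166 and the adhesion gene Cdh1 at 79.1 ± 39.4 against 0.297 ± 0.309. The visceral genes Ttr and Apoa1, which encode serum carrier proteins, stayed uncalled at 0.311 ± 0.403 and 0.350 ± 0.544 FPKM in colonies. The 14 parietal endoderm genes went both ways, with 7 higher, among them the laminin gene Lama1 at 114 ± 71.0 against 0.174 ± 0.146, and 4 lower, and the list did not pass (7 and 4 adjusted over the list alone; adjusted p = 0.391).

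The 22 fibroblast genes held 20 that were lower in colonies and none higher (21 lower adjusted over the list alone; median log2 difference -6.71; adjusted p = 5.24e-16, adjusted p = 0.0742 with an estimated correlation). The collagen gene Col1a1 was at 1.73 ± 0.976 against 2812 ± 23.0 FPKM (adjusted p = 2.9e-06). Dcn, a matrix proteoglycan, was at 0.405 ± 0.300 against 1087 ± 285 FPKM, S100a4 at 1.10 ± 0.579 against 1057 ± 470.3, and Postn, a matrix protein, at 0.520 ± 0.705 against 629 ± 286. All 8 genes of the smooth muscle contractile list were lower (8 adjusted over the list alone; adjusted p = 3.68e-05, adjusted p = 0.15 with an estimated correlation). An example was the actin-binding gene Tagln at 2.72 ± 1.41 against 1633 ± 485. Large decreases outside these lists included Bgn, also a matrix proteoglycan, at 2.12 ± 1.19 against 2799 ± 1274. Lox, which cross-links collagen, was at 1.19 ± 0.592 against 1852 ± 689, and Col12a1 at 0.778 ± 0.474 against 1131 ± 1044. Large increases outside the lists included the calcium-binding gene S100g at 4954 ± 2669 against 5.97 ± 5.82 and Bex1 at 670.4 ± 149.7 against 1.71 ± 0.686. Cyp26a1, which degrades retinoic acid, was at 325 ± 145 against 0.205 ± 0.188, and Igfbp1, which binds insulin-like growth factors, at 285 ± 191 against 0.0931 ± 0.0111.

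All 17 cell cycle genes were higher in colonies (17 adjusted over the list alone; median log2 difference 2.79; adjusted p = 2.79e-11, adjusted p = 0.131 with an estimated correlation). Examples were Mcm5, a replication licensing gene, at 49.3 ± 11.3 against 4.02 ± 2.77 FPKM and Ccnb1, a mitotic cyclin, at 109 ± 19.5 against 8.98 ± 1.12. Of 10 liver transcription factors that passed the filter, 6 were higher and none lower (6 adjusted over the list alone, adjusted p = 0.00216, adjusted p = 0.0742 with an estimated correlation). Examples were Foxa2 at 61.9 ± 30.2 against 0.103 ± 0.145 and Hnf4a at 6.97 ± 3.33 against 0.0313 ± 0.0442. Of 9 fetal liver genes, 6 were higher and none lower (6 adjusted over the list alone; adjusted p = 0.00481, adjusted p = 0.0742 with an estimated correlation). An example was Gpc3 at 296 ± 63.9 against 61.5 ± 1.32. The 10 genes of the pluripotency list that passed the filter held 6 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.029, adjusted p = 0.15 with an estimated correlation, and 0.0773 without fibroblasts 2). Examples were Lin28a, an RNA-binding protein, at 83.2 ± 23.7 against 0.0789 ± 0.112 and Sox2 at 15.4 ± 4.62 against 0.358 ± 0.260. Klf2 was the member that was lower, at 1.71 ± 1.83 against 42.9 ± 0.370. Nanog and Zfp42 in that list were not called, at 1.00 ± 0.642 and 0.389 ± 0.596 FPKM in colonies. Of 9 interferon response genes, 7 were lower and none higher (7 adjusted over the list alone; adjusted p = 0.000731, adjusted p = 0.279 with an estimated correlation). An example was Isg15 at 1.92 ± 2.86 against 65.0 ± 63.3. Of 9 cholangiocyte genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.0397, adjusted p = 0.279 with an estimated correlation). An example was the adhesion gene Epcam at 176 ± 88.4 against 0.215 ± 0.305. That list did not pass without colony 8 (0.0638) or without fibroblasts 2 (0.227). In the stress response list 3 of 12 genes were lower (2 adjusted over the list alone; adjusted p = 0.0424, adjusted p = 0.472 with an estimated correlation). It did not pass without colony 1 (0.0573), colony 6 (0.0578) or fibroblasts 2 (0.15), nor after median-ratio scaling (0.0668), without the filter (0.0793) or without the flow cell term (0.0688).

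With limma, 4854 of 14012 genes were called between colonies and fibroblasts, 2497 higher and 2357 lower, and 11 of 24 lists passed with the preset correlation. Without fibroblasts 2 the counts were 2564 higher and 1373 lower. On the HVN flow cells alone, which held fibroblasts 1 and colonies 1 to 3, 4518 genes were called, 3001 higher and 1517 lower. There 6 of the 11 lists did not pass, namely visceral endoderm (0.0562), pluripotency (0.0595), fetal liver (0.0595), cholangiocyte (0.0875), interferon response (0.0957, median from -2.71 to -1.27) and stress response (0.127). On the HJMKLALXX flow cell alone, which held fibroblasts 2 and colonies 4 to 8, 2661 genes were called. Over all genes the median log2 difference was 0.155, and -0.049 after median-ratio scaling, which moved the share of called genes that were higher from 51.4% to 39.9%.

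**Figure D1:**
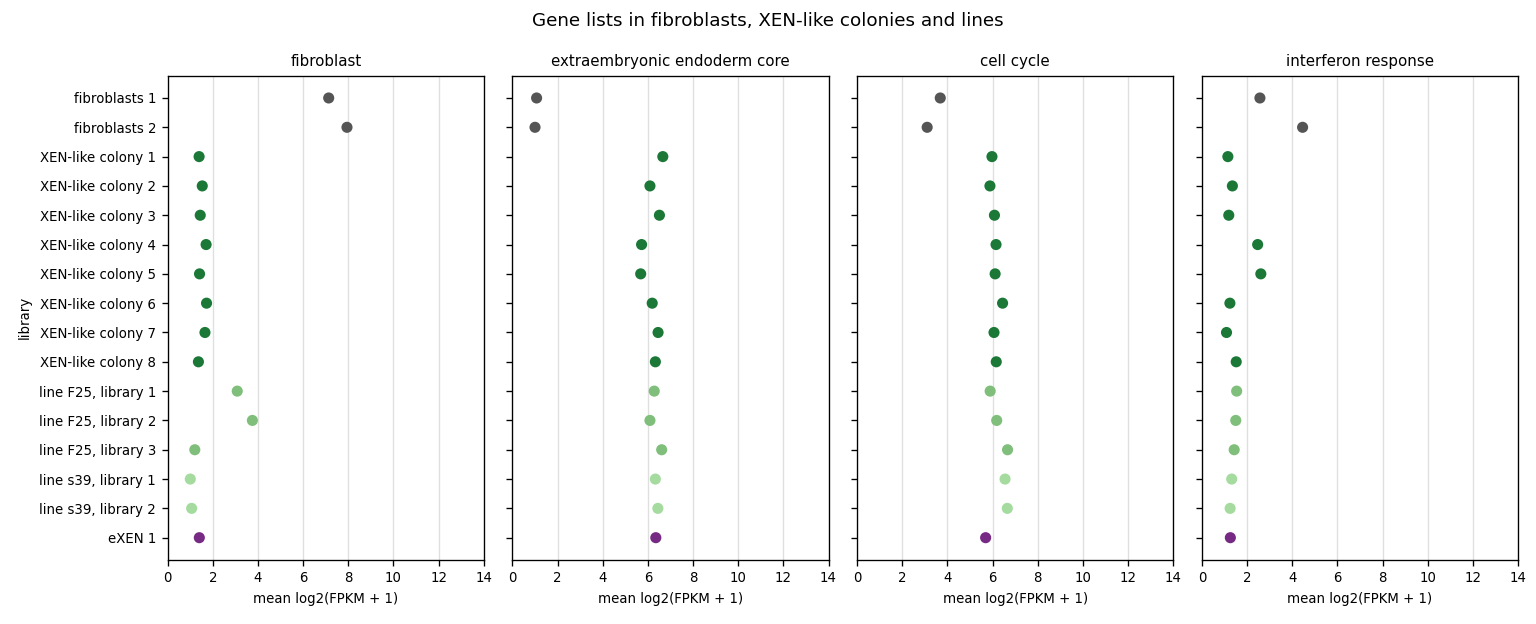
Mean log2(FPKM + 1) over the members of each gene list (horizontal axis), 1 point per library of the XEN-like table, with groups marked by colour. The 8 colonies lie between 5.68 and 6.66 on the extraembryonic endoderm core list, and both fibroblast libraries at 1.00 and 1.07.

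The second comparison asked how the expanded XEN-like lines, F25 and s39, differed from fibroblasts. As in the colonies, endoderm regulators and keratins were high and most genes of the fibroblast list low. Sox17 was at 637 ± 111 FPKM (SD, n = 5 libraries of 2 lines) against 0.142 ± 0.0580 (SD, n = 2) in fibroblasts (log2 difference 8.54 ± 0.35, SE, adjusted p = 3.61e-10). The highest log2 differences also included S100g at 2632 ± 1492 against 5.97 ± 5.82, Krt8 at 675 ± 123, Krt18 at 773 ± 144 against 1.53 ± 0.689, Bex1 at 669 ± 124 against 1.71 ± 0.686, Bex4 at 335 ± 94.5 against 0.624 ± 0.361, and the surface sialomucin Podxl at 259 ± 67.9 against 0.201 ± 0.104. Rhox5, an X-linked homeobox gene, varied more between the 5 libraries, at 501 ± 372 against 0.338 ± 0.478. Lower were Saa3 at 1.29 ± 0.783, Bgn at 2.26 ± 2.36, Lox at 1.22 ± 1.40, Dcn at 0.231 ± 0.314, Mmp3 at 0.110 ± 0.104, S100a4 at 2.66 ± 3.14 and Postn at 0.217 ± 0.301 FPKM, all against the fibroblast values above. Col1a1 was at 29.9 ± 44.6 over the lines, with 46.4 and 101 FPKM in F25 libraries 1 and 2 and 0.198 in F25 library 3 (log2 difference -8.75 ± 1.20, adjusted p = 5.43e-05).

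Of 16 core genes of extraembryonic endoderm, 14 were higher in the lines and none lower (14 adjusted over the list alone; median log2 difference 5.36; adjusted p = 1.39e-11, adjusted p = 0.067 with an estimated correlation). All 17 cell cycle genes were higher (17 adjusted over the list alone; adjusted p = 2.87e-12, adjusted p = 0.123 with an estimated correlation). Of 13 visceral endoderm genes, 8 were higher (10 adjusted over the list alone; adjusted p = 0.00236, adjusted p = 0.17 with an estimated correlation). Of 10 liver transcription factors, 5 were higher (6 adjusted over the list alone; adjusted p = 0.00515, adjusted p = 0.123 with an estimated correlation). None was lower in either list. The parietal endoderm list went both ways, with 5 higher and 4 lower of 14, and did not pass (7 and 4 adjusted over the list alone; adjusted p = 0.45). The fibroblast list held 20 of 22 genes lower (20 adjusted over the list alone; adjusted p = 3.37e-16, adjusted p = 0.123 with an estimated correlation). In the smooth muscle list 8 of 8 were lower (8 adjusted over the list alone; adjusted p = 3.93e-05, adjusted p = 0.17 with an estimated correlation). Of 9 interferon response genes, 6 were lower (6 adjusted over the list alone; adjusted p = 0.00261, adjusted p = 0.404 with an estimated correlation). Fetal liver genes were higher in 4 of 9 (4 adjusted over the list alone; adjusted p = 0.0311, adjusted p = 0.123 with an estimated correlation). This list did not pass without F25 library 1 (0.0544) or fibroblasts 2 (0.123). Stress response genes were lower in 4 of 12 (4 adjusted over the list alone; adjusted p = 0.0235, adjusted p = 0.462 with an estimated correlation). Without fibroblasts 2 the list did not pass (0.0539), nor without the flow cell term (0.1). With limma, 4741 of 14012 genes were called, 2674 higher and 2067 lower. Without fibroblasts 1 there were 1755 higher and 1778 lower, and without fibroblasts 2 there were 2848 and 1428. On the HVN flow cells alone, which held all lines and fibroblasts 1, 4823 were called, 3233 higher and 1590 lower. There the interferon (0.227, median from -2.50 to -0.53), fetal liver (0.129) and stress response (0.058) lists did not pass. The median log2 difference over all genes was 0.195, and -0.089 after median-ratio scaling, which moved the share that was higher from 56.4% to 40.1%.

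Lines and colonies were then compared with each other, to see what differed after expansion. Few genes differed. Ccnd3, a cyclin of the G1 phase (ENSMUSG00000034165, chromosome 17, 47505051 to 47599691), was at 132 ± 43.5 FPKM (SD, n = 5 libraries of 2 lines) in lines and 43.0 ± 8.90 (SD, n = 8) in colonies, a log2 difference of 1.42 ± 0.22 (SE) with an adjusted p of 0.0238. It was the 1 gene that the naming rule gave among 12 called (7 higher, 5 lower, of 14012, with 1920 at an unadjusted p under 0.05). The others were mostly ribosomal protein pseudogenes and unnamed gene models, whose reads can be shared with their parent genes. The call on Ccnd3 was lost without F25 library 2 (0.0576), s39 library 2 (0.168), s39 library 1 (0.132), colony 1 (0.124) or colony 2 (0.0686). Of 24 lists, the cholangiocyte list passed, with a median log2 difference of -0.33, no gene called, 1 lower when adjusted over the list alone, and an adjusted p of 0.0385 (adjusted p = 0.81 with an estimated correlation). It did not pass without s39 library 1 (0.085) or colony 1 (0.1), without the filter (0.101) or after median-ratio scaling (0.135). The count of 12 became 130 on the HVN flow cells alone and 35 without the flow cell term. It also moved by more than 1.5 times without F25 library 1 (30), s39 library 2 (5), s39 library 1 (6), colony 1 (6), colony 2 (6), colony 6 (45), colony 7 (22) or colony 8 (24).

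Within the lines, the change with passage number was fitted over 3 libraries of F25 (passages 5, 8 and 13) and 2 of s39 (passages 3 and 17). No gene was called by limma, with 66 genes at an unadjusted p under 0.05, and the slopes below are log2 per 10 passages with no member called in any list. The fibroblast list had a median slope of -0.53 (adjusted p = 2.33e-08, adjusted p = 0.51 with an estimated correlation) and the smooth muscle list -0.86 (adjusted p = 0.00111, adjusted p = 0.51 with an estimated correlation). The cell cycle list had a median slope of 0.21 (adjusted p = 0.000465, adjusted p = 0.59 with an estimated correlation). The first 3 of these lists rested on F25 library 3, the latest passage of that line, without which each turned direction with an adjusted p of 0.981, and the cell cycle list also failed without F25 library 1 (0.336). Cholangiocyte genes had a median slope of -0.48 (adjusted p = 0.0483, adjusted p = 0.528 with an estimated correlation), lost without F25 library 1 (0.336), F25 library 3 (0.119), s39 library 2 (0.523) or s39 library 1 (0.521), without the filter (0.146) and after scaling (0.0583). Stress response genes had -0.34 (adjusted p = 0.0483, adjusted p = 0.712 with an estimated correlation), lost without F25 library 3 (0.981), turned without F25 library 1 (0.486), and lost with a pseudocount of 0.1 (0.135), without the filter (0.157) and after scaling (0.0539). The number of genes called was 1 without F25 library 3, 2 without s39 library 1 and 2 without s39 library 2.

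The hepatocyte-like cells were compared with fibroblasts to see what the conversion had changed. Among the largest increases were single genes for mucosal peptides and serum proteins. Tff1, a secreted mucosal peptide (ENSMUSG00000024032, chromosome 17, 31161395 to 31165277), was at 17062 ± 6385 FPKM (SD, n = 4) against 2.62 ± 3.71 (SD, n = 2), a log2 difference of 12.65 ± 0.64 (SE) with an adjusted p of 1.97e-06. Apoa1, the main protein of high-density lipoprotein (ENSMUSG00000032083, chromosome 9, 46228580 to 46230466), was at 2207 ± 1820.3 against 0.354 ± 0.501 (log2 difference 10.43 ± 0.62, adjusted p = 5.27e-06). Afp, the fetal serum protein (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907), was at 1716 ± 974 against 0.936 ± 0.975 (log2 difference 9.57 ± 0.71, adjusted p = 1.61e-05). The matrix protease Mmp3 was at 0.231 ± 0.270 against 1796 ± 436 (log2 difference -10.52 ± 0.31, adjusted p = 4.01e-07). These 4 differences had the same direction in all 4 hepatocyte-like libraries, which the naming rule required of them.

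A further large increase was that of the mucosal peptide Tff3, at 3967 ± 1441 against 0.489 ± 0.692. The gastrokines Gkn1 and Gkn2, which the stomach lining secretes, were at 3652 ± 997 and 5304 ± 2015 against 0.662 ± 0.936 and 0.941 ± 1.33. Krt8 and Krt18 were at 2548 ± 966 and 2368 ± 1028 against 0.595 ± 0.352 and 1.87 ± 0.346. Of 19 genes for proteins that hepatocytes secrete, 16 were higher and none lower (17 adjusted over the list alone; median log2 difference 5.53; adjusted p = 7.78e-09, adjusted p = 0.218 with an estimated correlation). Examples were Ttr at 437 ± 201 against 0.0569 ± 0.0805 and Rbp4, a carrier of vitamin A, at 1108 ± 967 against 8.77 ± 5.21. Alb was not called, with 1899, 4514, 58.5 and 266 FPKM in the 4 libraries against 1.26 and 2.17 in fibroblasts. Of 15 visceral endoderm genes, 13 were higher and none lower (13 adjusted over the list alone; adjusted p = 1.85e-09, adjusted p = 0.0173 with an estimated correlation). Of 15 liver transcription factors, 7 were higher and none lower (8 adjusted over the list alone; adjusted p = 6.9e-06, adjusted p = 0.111 with an estimated correlation). Examples were Hnf4a at 59.1 ± 22.2 against 0.0108 ± 0.0153, and Foxa2 at 60.1 ± 25.5 while listed at 0 in both fibroblast libraries. Of 18 metabolic enzymes and receptors of hepatocytes, 3 were higher and the list did not pass (3 adjusted over the list alone; adjusted p = 0.156). Of 20 genes of drug and bile metabolism, 5 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.00704, adjusted p = 0.456 with an estimated correlation). An example was Cyp3a13 at 18.3 ± 9.63 against 0.0896 ± 0.0131. Of 9 fetal liver genes, 4 were higher and 1 lower, and the list did not pass (5 and 2 adjusted over the list alone; adjusted p = 0.184). Cyp3a11, which was not called, was at 169, 613, 1.03 and 0.326 FPKM in the 4 libraries.

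Core genes of extraembryonic endoderm were higher in 14 of 16 (14 adjusted over the list alone; adjusted p = 7.78e-09, adjusted p = 0.182 with an estimated correlation). An example was Epcam at 242 ± 78.4 against 0.0915 ± 0.129. Of 9 cholangiocyte genes, 7 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 1.1e-05, adjusted p = 0.117 with an estimated correlation). Examples were the keratin Krt19 at 1429 ± 577 against 1.06 ± 0.0905 and the tight junction gene Cldn4 at 826 ± 335 against 0.0635 ± 0.00890. Spp1 was lower, at 59.4 ± 61.3 against 3177 ± 318. Of 9 genes of intestinal endoderm, 7 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.000235, adjusted p = 0.182 with an estimated correlation). An example was the mucin gene Muc13 at 70.2 ± 63.1 against 0.0936 ± 0.0388. Of 11 stress response genes, 5 were higher and none lower (5 adjusted over the list alone; adjusted p = 0.0152, adjusted p = 0.182 with an estimated correlation). The largest of these differences, in Fos at 214 ± 241 against 11.1 ± 3.44, was no longer called without fibroblasts 1 (0.0925) or fibroblasts 2 (0.158).

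All 21 fibroblast genes tested were lower in hepatocyte-like cells (21 adjusted over the list alone; median log2 difference -6.38; adjusted p = 2.76e-18, adjusted p = 0.0605 with an estimated correlation). Examples were Col1a2 at 2.40 ± 4.37 against 952 ± 410.0, the gelatinase Mmp2 at 0.345 ± 0.365 against 585 ± 99.2 and Thy1 at 0.0152 ± 0.0305 against 279 ± 69.8. Of 8 smooth muscle genes, 7 were lower (7 adjusted over the list alone; adjusted p = 4.59e-05, adjusted p = 0.218 with an estimated correlation). An example was Tagln at 14.1 ± 22.3 against 714 ± 217. Outside the lists, Bgn was at 3.85 ± 5.21 against 2293 ± 482, Mmp13 at 0.0768 ± 0.124 against 585 ± 453 and Ptx3 at 3.38 ± 4.16 against 952 ± 421. The fibroblast libraries of this table also held transcripts of macrophages. Lyz2, the lysozyme of myeloid cells, was at 1.66 ± 1.45 in hepatocyte-like cells against 4663 ± 4474. The chemokine gene Ccl6 was at 0.127 ± 0.207 against 461 ± 430.2 and Tyrobp, a myeloid adaptor, at 0.0742 ± 0.148 against 207 ± 186. Of 9 macrophage genes, 7 were lower in hepatocyte-like cells (8 adjusted over the list alone; adjusted p = 6.28e-05, adjusted p = 0.377 with an estimated correlation). Of 10 Kupffer cell genes, 6 were lower (6 adjusted over the list alone; adjusted p = 0.0038, adjusted p = 0.454 with an estimated correlation). Pan-neuronal genes that passed the filter, which values in fibroblasts help decide, were lower in 6 of 9 (6 adjusted over the list alone; adjusted p = 0.00116, adjusted p = 0.182 with an estimated correlation, and 0.0819 without the filter, where the median log2 difference went from -2.16 to -0.04). An example was Gap43 at 0.121 ± 0.183 against 21.0 ± 5.22. Stellate cell genes were lower in 3 of 6 (4 adjusted over the list alone; adjusted p = 0.0107, adjusted p = 0.218 with an estimated correlation). With limma, 4123 of 15657 genes were called, 1779 higher and 2344 lower. On flow cell HH2TTALXX alone 4126 were called, and it held both fibroblast libraries and hepatocyte-like libraries 3 and 4. The count was 1604 without fibroblasts 1 and 1528 without fibroblasts 2.

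The next comparison asked how close the hepatocyte-like cells came to hepatocytes, and these differed in most gene groups of the mature liver. Across genes, libraries 1 and 2 correlated with hepatocytes at 0.615 to 0.635 and libraries 3 and 4 at 0.539 to 0.55. All 4 correlated more with fibroblasts, at 0.641 to 0.714. Cyp2e1, a cytochrome that oxidises ethanol (ENSMUSG00000025479, chromosome 7, 140763739 to 140774987), was listed at 0 in all 4 hepatocyte-like libraries and at 2141 ± 624 FPKM (SD, n = 2) in hepatocytes (adjusted p = 1.08e-07). Of 18 metabolic enzymes and receptors, 17 were lower and none higher (17 adjusted over the list alone; median log2 difference -6.52; adjusted p = 2.14e-23, adjusted p = 0.0224 with an estimated correlation). An example was Tdo2, which degrades tryptophan, at 0.191 ± 0.382 (SD, n = 4) against 573 ± 352. Of 15 liver transcription factors, 12 were lower (12 lower and 1 higher adjusted over the list alone; adjusted p = 8.69e-13, adjusted p = 0.0224 with an estimated correlation). Examples were the nuclear receptor Nr1i3 at 0.111 ± 0.146 against 96.8 ± 23.0 and the bile acid receptor Nr1h4 at 1.54 ± 0.694 against 33.6 ± 16.4. Of 20 genes of drug and bile metabolism, 15 were lower (16 adjusted over the list alone; adjusted p = 1.83e-18, adjusted p = 0.132 with an estimated correlation). Of 19 secreted proteins, 17 were lower (17 adjusted over the list alone; adjusted p = 3.57e-18, adjusted p = 0.132 with an estimated correlation). None was higher in either list. The member Alb was not called and was listed at 0 in hepatocytes 1 and at 51325 FPKM in hepatocytes 2. Apoa2 was at 71.5 ± 36.2 against 27224 ± 2710.1 and Serpinc1, which encodes antithrombin, at 16.2 ± 20.3 against 4108 ± 579.9. Among the largest decreases, Serpina3k was at 0.128 ± 0.0841 against 2035 ± 1682 and Serpina6, the corticosteroid carrier, at 0.378 ± 0.757 against 8258 ± 10885. The other large decreases were in the major urinary protein genes Mup2, Mup3, Mup9, Mup10 and Mup14, whose near-identical sequences share reads, so that values of single genes are not specific.

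Higher in hepatocyte-like cells were Tff1, Gkn1, Gkn2 and Psca, each listed at 0 in both hepatocyte libraries and at 17062 ± 6385, 3652 ± 997, 5304 ± 2015 and 1104 ± 512 FPKM (SD, n = 4). Tff3 was at 3967 ± 1441 against 3.51 ± 0.765 (SD, n = 2). The calcium-binding genes S100a6 and S100a11 were at 2066 ± 1299.6 and 2065 ± 953, with S100a6 at 0.115 ± 0.163 and S100a11 at most 2.1 in hepatocytes. Of 9 cholangiocyte genes, 7 were higher (7 adjusted over the list alone; adjusted p = 0.00219, adjusted p = 0.156 with an estimated correlation). Examples were Krt19 at 1429 ± 577 against 0.0840 ± 0.119 and Epcam at 242 ± 78.4 against 0.0623 ± 0.0881. Of 9 fetal liver genes, 7 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0334, adjusted p = 0.279 with an estimated correlation, and 0.0561 without hepatocyte-like library 4). Examples were H19 at 5413 ± 4472 against 7.61 ± 4.95, Igf2 at 913 ± 339 against 0.893 ± 0.213 and Afp at 1716 ± 974 against 8.88 ± 1.57. All 10 genes of the p53 and senescence list were higher (10 adjusted over the list alone; adjusted p = 0.00144, adjusted p = 0.156 with an estimated correlation). Examples were the cell cycle inhibitors Cdkn1a at 235 ± 82.7 against 3.06 ± 3.70 and Cdkn2a at 106 ± 47.5 while listed at 0 in hepatocytes. Cell cycle genes were higher in 14 of 17 (15 adjusted over the list alone; adjusted p = 0.0261, adjusted p = 0.667 with an estimated correlation, and 0.0652 without hepatocytes 2). An example was Cdk1 at 45.5 ± 33.3 against 0.399 ± 0.0941. Core genes of extraembryonic endoderm were higher in 12 of 16 (14 adjusted over the list alone; adjusted p = 0.00334, adjusted p = 0.495 with an estimated correlation). An example was Sox17 at 139 ± 119 against 0.487 ± 0.570. Parietal endoderm genes were higher in 11 of 14 (12 adjusted over the list alone; adjusted p = 0.0193, adjusted p = 0.542 with an estimated correlation, and 0.0652 without hepatocytes 2). Stress response genes were higher in 8 of 11 (9 adjusted over the list alone; adjusted p = 0.0193, adjusted p = 0.156 with an estimated correlation). An example was Ddit3 at 204 ± 162 against 3.28 ± 1.75.

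Of the lists for other cells of the liver and for blood, the Kupffer, endothelial, macrophage and blood lists passed as lower. This is relative to all genes, with their median log2 difference of 0.937. The stellate list did not pass, with none of 6 genes called, a median log2 difference of 0.13 while the test pointed down, and an adjusted p of 0.198. Of 10 Kupffer cell genes, 7 were lower and 1 higher (7 and 1 adjusted over the list alone; adjusted p = 5.05e-06, adjusted p = 0.282 with an estimated correlation). Of 10 genes of liver endothelium, 4 were lower (2 adjusted over the list alone; adjusted p = 0.000293, adjusted p = 0.352 with an estimated correlation, and 0.0525 without hepatocytes 1, where the median went from -0.88 to 0.07). Macrophage genes were lower in 4 of 9 and higher in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.00287, adjusted p = 0.495 with an estimated correlation, 0.11 without hepatocytes 1 and 0.0618 after median-ratio scaling). Blood genes were lower in 3 of 8 and higher in 1 (3 and 1 adjusted over the list alone; adjusted p = 0.00287, adjusted p = 0.156 with an estimated correlation, and 0.0533 after scaling). Visceral endoderm genes went both ways, 5 higher and 6 lower of 15 (5 and 6 adjusted over the list alone; adjusted p = 0.00693, adjusted p = 0.132 with an estimated correlation, and 0.143 after scaling). Examples were Cdh1 at 155 ± 41.5 against 3.38 ± 2.99 and Apob, the main protein of low-density lipoprotein, at 8.73 ± 6.85 against 714 ± 13.5. Astrocyte genes, of which hepatocytes express some, were higher in 1 and lower in 3 of 7 (1 and 3 adjusted over the list alone; adjusted p = 0.0179, adjusted p = 0.156 with an estimated correlation). This was lost without hepatocytes 1 (0.0975), after scaling (0.185) and without the filter (0.0667). With limma, 7649 of 15657 genes were called, 6468 higher and 1181 lower. After median-ratio scaling, which brought the median over all genes from 0.937 to 0.131, 4695 genes were called with 54.5% of them higher in place of 84.6%. Hepatocytes and hepatic tissue were sequenced on a flow cell that held no hepatocyte-like library, so flow cell and group cannot be told apart here.

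**Figure D2:**
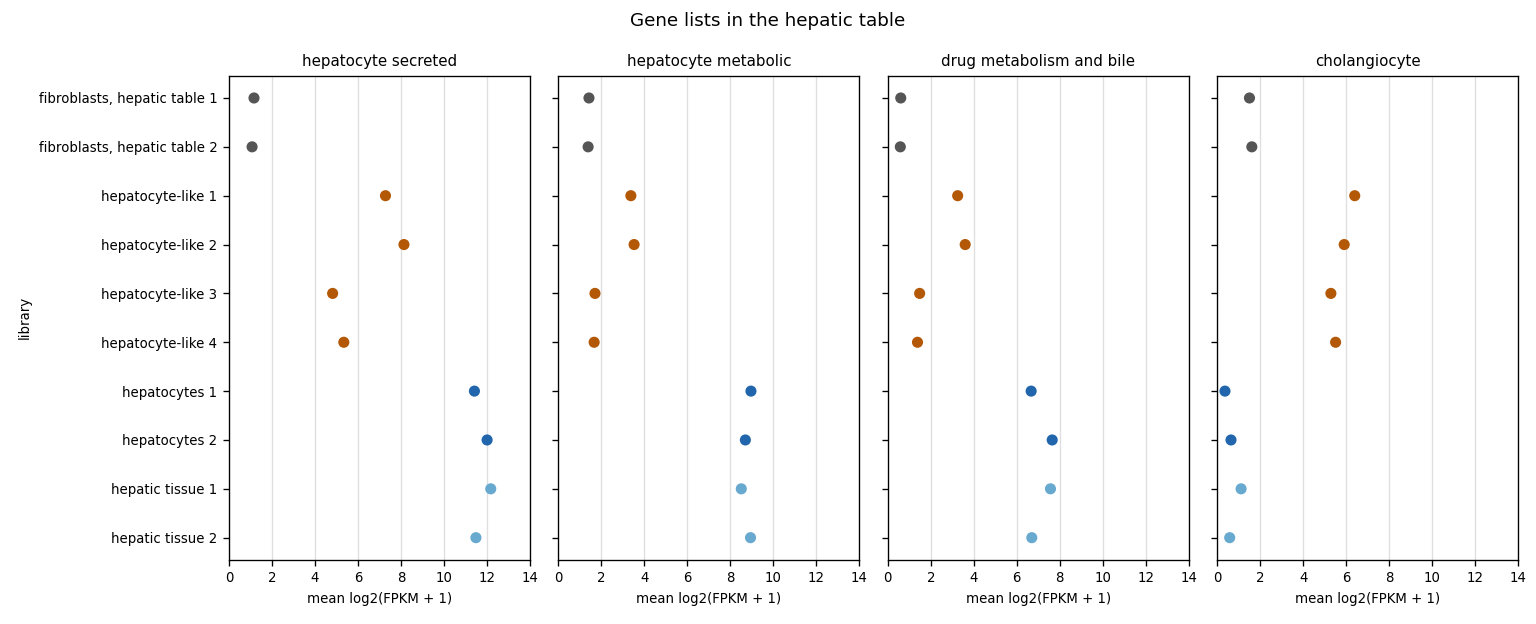
Mean log2(FPKM + 1) over the members of each gene list (horizontal axis), 1 point per library of the hepatic table, with groups marked by colour. On the hepatocyte metabolic list the 4 hepatocyte-like libraries lie between 1.66 and 3.52, hepatocytes at 8.70 and 8.96, and hepatic tissue at 8.51 and 8.94.

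Against hepatic tissue, the other reference for the liver, the mature gene groups were again lower in hepatocyte-like cells. Metabolic enzymes and receptors were lower in 17 of 18 (17 adjusted over the list alone; adjusted p = 1.62e-22, adjusted p = 0.0279 with an estimated correlation). Liver transcription factors were lower in 12 of 15 (12 lower and 1 higher adjusted over the list alone; adjusted p = 8.52e-12, adjusted p = 0.0279 with an estimated correlation). Secreted proteins were lower in 17 of 19 (18 adjusted over the list alone; adjusted p = 5.07e-18, adjusted p = 0.102 with an estimated correlation). Genes of drug and bile metabolism were lower in 15 of 20 (16 adjusted over the list alone; adjusted p = 5.07e-18, adjusted p = 0.102 with an estimated correlation). Cyp2e1 was at 3096 ± 1103 FPKM (SD, n = 2) in tissue and listed at 0 in hepatocyte-like cells. H19 was at 5413 ± 4472 (SD, n = 4) against 5.25 ± 2.43, Krt19 at 1429 ± 577 against 0.531 ± 0.00162 and Zg16, a lectin-like secretory gene, at 2099 ± 2851 while listed at 0 in tissue. Liver endothelial genes were lower in 8 of 10 (8 adjusted over the list alone; adjusted p = 2.17e-08, adjusted p = 0.147 with an estimated correlation). Kupffer cell genes were lower in 8 of 10 (8 adjusted over the list alone; adjusted p = 7.38e-08, adjusted p = 0.179 with an estimated correlation). Macrophage genes were lower in 5 of 9 (6 adjusted over the list alone; adjusted p = 3.35e-05, adjusted p = 0.281 with an estimated correlation). Stellate cell genes were lower in 2 of 6 (2 adjusted over the list alone; adjusted p = 0.000295, adjusted p = 0.102 with an estimated correlation). Blood genes were lower in 5 of 8 and higher in 1 (5 and 1 adjusted over the list alone; adjusted p = 4.66e-06, adjusted p = 0.102 with an estimated correlation). Examples in tissue were the scavenger receptor Stab2 at 12.3 ± 0.908 against 0.0859 ± 0.172 and the Kupffer lectin Clec4f at 73.2 ± 31.3 while listed at 0 in hepatocyte-like cells.

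Higher than in tissue were cholangiocyte genes in 6 of 9 (6 adjusted over the list alone; adjusted p = 0.00274, adjusted p = 0.147 with an estimated correlation). Genes of p53 and senescence were higher in 9 of 10 (10 adjusted over the list alone; adjusted p = 0.000689, adjusted p = 0.112 with an estimated correlation). Stress response genes were higher in 9 of 11 (10 adjusted over the list alone; adjusted p = 0.0112, adjusted p = 0.114 with an estimated correlation). Cell cycle genes were higher in 14 of 17 (15 adjusted over the list alone; adjusted p = 0.0184, adjusted p = 0.604 with an estimated correlation). Core genes of extraembryonic endoderm were higher in 13 of 16 (14 adjusted over the list alone; adjusted p = 0.00438, adjusted p = 0.41 with an estimated correlation). Fetal liver genes were higher in 7 of 9 and lower in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0277, adjusted p = 0.208 with an estimated correlation). Parietal endoderm genes were higher in 11 of 14 (11 adjusted over the list alone; adjusted p = 0.0491, adjusted p = 0.597 with an estimated correlation). The call was lost without hepatocyte-like library 4 (0.0776), without tissue 1 (0.117) and with a term for the libraries without Y-linked transcripts (0.0532), which was chosen after the data were seen. Visceral endoderm genes went both ways, 5 higher and 6 lower of 15 (6 and 7 adjusted over the list alone; adjusted p = 0.00723, adjusted p = 0.102 with an estimated correlation, and 0.139 after scaling). Astrocyte genes did too, with 1 higher and 3 lower of 7 (1 and 3 adjusted over the list alone; adjusted p = 0.00994, adjusted p = 0.102 with an estimated correlation, and 0.13 after scaling). For the fibroblast list the median log2 difference was 0.14 while the test pointed down (1 higher and 2 lower of 21, none adjusted over the list alone; adjusted p = 0.0102, adjusted p = 0.385 with an estimated correlation, and 0.183 after scaling). With limma, 7867 of 15657 genes were called, 6624 higher and 1243 lower, with a median log2 difference over all genes of 0.957. After median-ratio scaling the median was 0.167 and 4951 genes were called, 53.4% of them higher in place of 84.2%, and flow cell and group cannot be told apart here either.

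Hepatocytes and hepatic tissue were compared as references for each other. The lists that passed were all lower in hepatocytes and held no called gene, and the cholangiocyte list did not pass (adjusted p = 0.337). Blood genes had a median log2 difference of -2.96 (none called, 4 of 8 lower adjusted over the list alone; adjusted p = 4.97e-11, adjusted p = 0.0363 with an estimated correlation). An example was the hemoglobin gene Hbb-bs at 29.1 ± 14.7 FPKM (SD, n = 2) against 2230.0 ± 2538 (SD, n = 2). Stellate cell genes had -1.47 (none called, 3 of 6 lower adjusted over the list alone; adjusted p = 4.97e-11, adjusted p = 0.0363 with an estimated correlation). Liver endothelial genes had -1.50 (none called, and none adjusted over the list alone; adjusted p = 1.31e-11, adjusted p = 0.27 with an estimated correlation), and lost the call without hepatocytes 2 (0.0639). Macrophage genes had -1.70 (adjusted p = 5.08e-05, adjusted p = 0.809 with an estimated correlation). Kupffer cell genes had -1.24 (adjusted p = 0.000223, adjusted p = 0.809 with an estimated correlation). In neither list was a gene called, over all genes or adjusted over the list alone. Both turned direction without hepatocytes 2, with adjusted p values of 0.722 and 0.00475. Fibroblast genes had -0.48 (none called, and none adjusted over the list alone; adjusted p = 0.000789, adjusted p = 0.799 with an estimated correlation), lost without hepatocytes 2 (0.349) or tissue 2 (0.0814). With limma 1 gene was called, the unnamed gene model Gm13021, with a log2 difference of -2.58 ± 0.25 (SE, adjusted p = 0.0322). It falls outside the naming rule and was chosen after its values were seen. At an unadjusted p under 0.05 there were 334 genes. The count was 3 without hepatocytes 1, 2 without tissue 1, and 0 without hepatocytes 2 or tissue 2 (249 and 605 at an unadjusted p under 0.05).

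The neuronal libraries had no replicates within a table, so the differences below carry no test, and lists are set against 10000 random lists of the same size and expression. TauEGFP colonies 1 held neuronal transcripts far above the fibroblasts of the same table. All 19 pan-neuronal genes were higher, with a median log2 difference of 4.37, above every random list, and the synapse and channel list had 2.37 over 16 members. Cartpt, a neuropeptide precursor (ENSMUSG00000021647, chromosome 13, 99898489 to 99901091), was at 469 FPKM and listed at 0 in fibroblasts 3. Vgf, a neurosecretory protein (ENSMUSG00000037428, chromosome 5, 137026392 to 137033351), was at 843 against 1.22. Contractile genes were low, with Acta2 at 1.24 against 2955, Tagln at 0.875 against 2026 and Actg2 at 0.136 against 412. The smooth muscle list had a median of -4.86. The cell cycle list had a median of -2.22 over 17 members and the fibroblast list -1.75 over 22, both below every random list. Proneural factors had 1.91 over 9 members. Among the largest differences were also Gkn1 at 310.0, Gkn2 at 318, Spink4 at 288 and Gpx2 at 257 FPKM, all listed at 0 in fibroblasts 3. The intestinal endoderm list had a median of 1.83 over 7 members, with 5 higher and 1 lower. The core list of extraembryonic endoderm had a median of 3.93 over 15 members and the interferon list 2.72 over 10. By at least 2 on the log2 scale, 1455 genes were higher and 379 lower of 15010.

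Set against primary neurons 1 of the same table, TauEGFP colonies 1 lacked genes of the cerebral cortex. All 14 cortical identity genes were lower, with a median log2 difference of -4.55, such as Neurod2 (ENSMUSG00000038255, chromosome 11, 98325415 to 98329648) at 0.0510 against 142 FPKM. All 13 proneural factors were lower, with a median of -1.94. The pan-neuronal list differed less, with a median of -0.59 over 19 members, and the synapse and channel list had -0.91 over 18. Fibroblast genes were higher in 18 of 21, with a median of 4.79, and the p53 and senescence list had 3.90 over 10 members. In TauEGFP colonies 1 Saa3 was at 5296, Cdkn2a at 463, Ccl8 at 635 and Mmp13 at 282 FPKM, each listed at 0 in primary neurons 1, and Lcn2 at 605 against 0.432. Primary neurons 1 held hemoglobin transcripts, with Hba-a1 at 5321 and Hbb-bs at 3416 FPKM, and more macrophage transcripts, with a median of -3.42 over 9 members. Against brain, the pan-neuronal list had a median of -1.22, the synapse and channel list -1.80 and the cortical identity list -2.42.

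The neuronal cells induced directly by FICB also held neuronal genes above fibroblasts 3, with a pan-neuronal median of 3.26 over 17 members and a synapse and channel median of 2.96 over 13, both above every random list. Among them were Syp, a synaptic vesicle protein, at 135 against 0.0393 FPKM, Snap25, which acts in vesicle fusion, at 98.7 against 0.118, and the secretory gene Scg2 at 195 against 0.0444. The cell cycle list had a median of -2.83. TauEGFP colonies 1 exceeded the FICB cells by a pan-neuronal median of 1.46 over 19 members, by 3.48 on the core list of extraembryonic endoderm over 15 and by 4.07 on the cholangiocyte list over 9. Olfm4 was at 264 against 0.0592, Wfdc2 at 340.0 against 0.372, and Tff2 at 236 while listed at 0 in FICB cells. FICB cells held more Penk, an opioid precursor, at 1151 against 84.5, and more Sfrp2, at 251 against 9.89.

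The other neuronal table held 1 library of each group on different flow cells, so flow cell and group cannot be told apart there. In it TauEGFP colonies 2 held Stmn2, a growth cone protein, at 342 FPKM against 1.01 in the library labelled primary neurons 2, and a pan-neuronal median 4.40 higher over 19 members. That library held macrophage and microglia transcripts, with C1qa at 1149.7, Tyrobp at 810.1 and Trem2 at 483 FPKM, each listed at 0 in TauEGFP colonies 2, and Lyz2 at 3616 against 2.02. Its astrocyte list was also higher, with a median difference of -3.38 for the colonies. Hoxb7, Hoxb8 and Hoxb9, which mark trunk levels of the body axis, were at 109.7, 130.5 and 162 FPKM in TauEGFP colonies 2.

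Taking both tables together, TauEGFP colonies were tested against primary neurons (n = 2 each, table as a block). No gene of 13625 was called by limma, with 750 at an unadjusted p under 0.05 (490 higher, 260 lower) and 0.645 as the smallest adjusted p. Simulated changes of up to 6 on the log2 scale were not recovered at this size either, so the absence of calls does not show that the groups were alike. No list member was called, and none of the 14 lists that passed with the preset correlation passed with an estimated one. The fibroblast list had a median log2 difference of 4.11 (17 of 21 higher adjusted over the list alone; adjusted p = 5.07e-21, adjusted p = 0.517 with an estimated correlation). The parietal endoderm list had 2.49 (8 of 14 higher adjusted over the list alone; adjusted p = 3.33e-11, adjusted p = 0.517 with an estimated correlation). The fetal liver list had 3.11 (5 of 7 higher adjusted over the list alone; adjusted p = 2.61e-08, adjusted p = 0.517 with an estimated correlation). The core list of extraembryonic endoderm had 3.17 (3 of 11 higher adjusted over the list alone; adjusted p = 4.03e-06, adjusted p = 0.517 with an estimated correlation). The macrophage list had -5.99 (7 of 8 lower adjusted over the list alone; adjusted p = 3.65e-12, adjusted p = 0.517 with an estimated correlation), with transcripts that the library labelled primary neurons 2 held. The cortical identity list had -1.65 (4 of 10 lower adjusted over the list alone; adjusted p = 3.63e-09, adjusted p = 0.517 with an estimated correlation). The pan-neuronal list had 2.04 (none adjusted over the list alone; adjusted p = 4.03e-06, adjusted p = 0.653 with an estimated correlation), from -0.59 in the first table and 4.40 in the other.

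**Figure D3:**
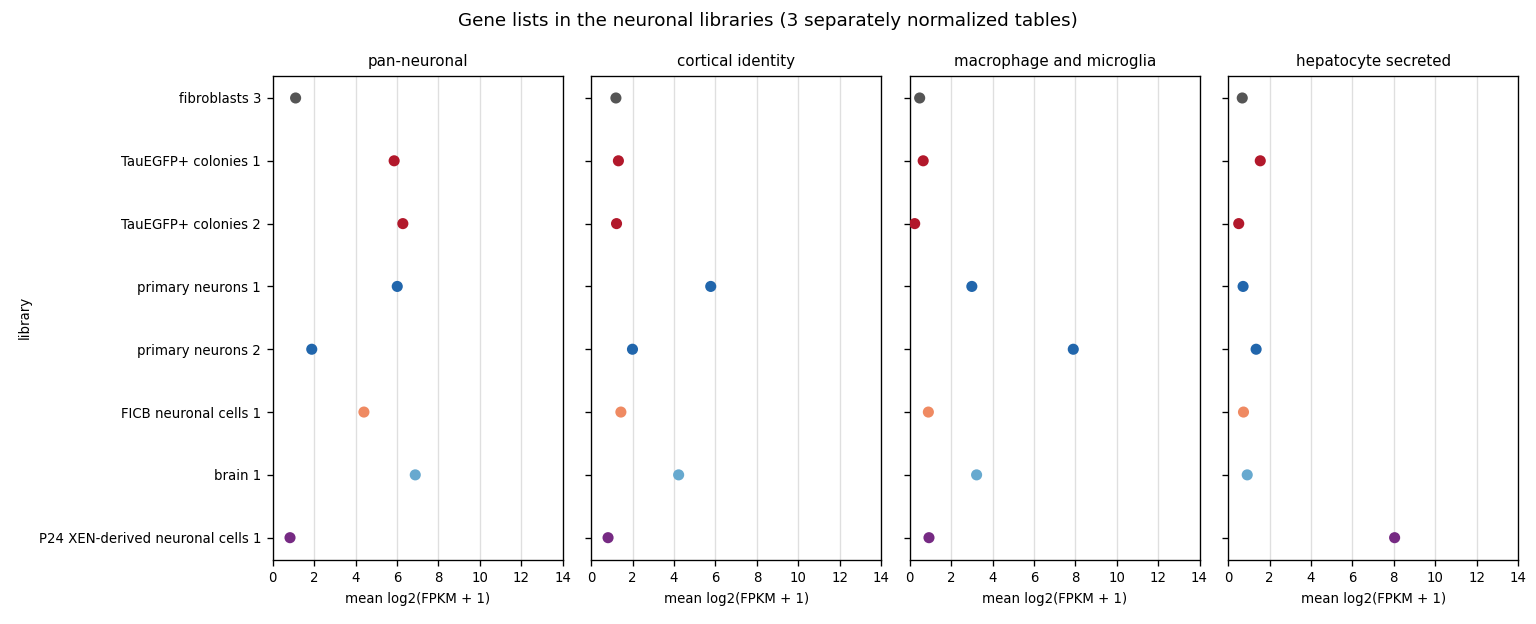
Mean log2(FPKM + 1) over the members of each gene list (horizontal axis), 1 point per library of the neuronal tables, with libraries marked by colour. On the pan-neuronal list TauEGFP colonies 1 and 2 lie at 5.86 and 6.28, primary neurons 1 at 6.01, the library labelled primary neurons 2 at 1.88 and fibroblasts 3 at 1.10.

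The single library of eXEN cells was compared with the groups of its table. Across genes, which are not independent replicates, its Pearson correlation of log2 values was 0.884 to 0.954 with the 8 colonies, 0.889 to 0.918 with F25, 0.935 to 0.946 with s39 and 0.637 to 0.725 with fibroblasts. Gata6 was at 45.9, Ihh at 168 and Lama1 at 198 FPKM, all chosen after their values were seen, in this single library.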

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

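Of the tests in this part, those on the library labelled P24 XEN-derived neurons, on the library labelled primary neurons 2 and on swapped hepatic labels were chosen after the results were seen. The regrouping of libraries and the list of sex-biased liver genes were fixed before the results they measure.

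Among colonies and among hepatocyte-like libraries, 255 series of values of named genes and list members were searched for a library far from the others of its group. Of these, 31 series (12.2%) had a gap beyond the 95% critical value, while chance flags about 1 in 20 and would give 12.8 series of the 255. In colony 6, Cdh1 was low at 6.70 FPKM (48.7 in the nearest other colony) and Lin28b was high at 12.5 (nearest 4.62), with Apoa1 at 1.64 and Ncam1 at 0.968. Colony 4 had the highest Postn at 2.18 and Rgs5 at 0.186. The other colonies with a high value were colony 2 with S100a8 at 0.433, colony 1 with Tyrobp at 0.317 and colony 7 with Zfp42 at 1.78. Hepatocyte-like library 3 had 16 of the 31 gaps. It was high for the contractile genes Acta2 at 116 (nearest 1.87) and Cnn1 at 4.56 (nearest 0.0537) and for Thbd at 44.0 (nearest 3.50), and low for Cldn4 at 334 (nearest 935) and Usp18 at 39.7 (nearest 84.6). Its other high values were small, with Colec11 at 1.36, Emx2 at 1.02, Tdo2 at 0.764, Alas2 at 0.402, Stab2 at 0.344, Tyrobp at 0.297, C1qc at 0.191, Actc1 at 0.0741, S100b at 0.0734, Thy1 at 0.0609 and Bhlhe22 at 0.0582. Library 2 was high for Lum at 1.90 and Syt1 at 0.540, library 1 for Mup14 at 0.213 and Mup2 at 0.155, and library 4 for Serpina6 at 1.51 and Mup9 at 0.202. The 3 Mup genes share reads with near-identical genes, so these values are not specific to them. Of these values 17 are under 1 FPKM, where a few fragments decide the gap, and genes of 1 library are not independent of each other. No explanation was tested for them.

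Lines F25 and s39 differed from each other in an imprinted pair of genes, by a test within the same model. The log2 difference of F25 minus s39 was 4.27 in Igf2 (means 1879 and 89.7 FPKM, adjusted p = 0.000123) and 3.69 in H19 (means 5895 and 489.5, adjusted p = 0.00645), over 3 libraries of F25 and 2 of s39. The difference between lines was examined after the data were seen, and with 1 line on each side no cause was tested.

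The count of 12 genes between lines and colonies was set against 99 random regroupings of the same 13 libraries. With the real one included, 5 of 100 groupings gave at least as many genes, so chance cannot be excluded as an explanation of that count. The regroupings take the libraries as exchangeable and break up the lines, which the real grouping keeps whole. They also mix flow cells, while all line libraries lie on HVN flow cells with 3 of 8 colonies. The highest other count was 128, with 112, 38 and 34 in the next ones. Counts so far above 12 point to a structure among the libraries that crosses the labels. The groupings with 128 and 112 genes joined F25 libraries with colonies 2 and 6, but 10 others that also did so gave at most 1 gene, so which libraries raise the count is not known. Within the HVN flow cells 130 genes were called. There the 3 colonies held Eif2s3y without Xist and the F25 libraries Xist alone, so sex of the cells is tied to line in that count.

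The library labelled P24 XEN-derived neurons, the 1 library of its table, was outside every comparison and held transcripts of endoderm and liver. Afp was at 2924, Alb at 1429 and Tff1 at 2723 FPKM, with Tff3 at 4724, Krt8 at 2307 and Hnf4a at 74.6. All 19 secreted hepatocyte proteins reached 10 FPKM, with a median of 410.4. The pan-neuronal list had a median of 0.427, with 1 of 19 genes at 10 or more, and Map2 was at 0.767, against 93.3 and 107 in TauEGFP colonies 1 and 2. A mislabelled sample is a candidate explanation. The lowest correlation with a hepatocyte-like library (0.921) exceeded the highest with a neuronal library or brain (0.865, TauEGFP colonies 1) by 0.056, and its table lists the same genes as the hepatic table. These correlations run across genes and tables. XEN-like cells that stayed unconverted are argued against, since the median secreted protein was 97.6 times its highest value in a XEN-like colony or line, and between 12.6 and 1338 times over the 17 members listed in both tables, with 1 FPKM added to every value. It stays open whether the label is wrong or whether a neuronal culture consisted mainly of hepatocyte-like or gut-like cells, which no value in the tables decides. No biological explanation was tested beyond these.

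The library labelled primary neurons 2 held glial transcripts and few neuronal ones, with Gfap at 2688 and Apoe at 16291 FPKM. Its pan-neuronal genes had a median of 2.88% of their values in primary neurons 1, and 5 of 18 that reached 10 there also did so here. A swap with TauEGFP colonies 2 is argued against, since only 1 of the 14 cortical genes that primary neurons 1 held at 10 FPKM or more reached that level in TauEGFP colonies 2. RNA of astrocytes and microglia in place of neurons may explain the values. The median of the microglia list was 322 FPKM, against 8.68 in primary neurons 1 and 10.1 in brain, and that of the astrocyte list 122, against 4.67 and 37.9. These values lie in different tables, which were made separately. Both lists were fixed before the data were examined, and brain expresses members of both. A glial culture under a wrong label and a neuronal culture overgrown by glia would give the same values, so these cannot be told apart. The comparison of TauEGFP colonies with primary neurons therefore rests on a reference of uneven content.

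Hepatocyte and hepatic tissue libraries resembled each other across the labels. Over 10870 genes, hepatocytes 1 correlated with tissue 2 at 0.975 and hepatocytes 2 with tissue 1 at 0.945, against 0.879 between the hepatocyte libraries and 0.892 between the tissue libraries. By at least 1 on the log2 scale, 1023 genes separated the libraries in the crossed way, 102 by the labels and 13 by number. Sex of the animals may explain this as a biological difference. Of 17 genes listed beforehand as sex-biased in mouse liver, 15 were higher in both libraries of the listed sex, where libraries were sexed by Xist and Eif2s3y, with Cyp2b9 and Selenbp2 as the exceptions. A1bg was at 1262 and 1258 FPKM in hepatocytes 1 and tissue 2 against 0.809 and 0.966 in the others, and Cyp4a12a at 1.31 and 0.599 against 151 and 188. Swapped labels between hepatocytes and tissue stay open. Of 7 blood genes at 10 FPKM or more, 4 were higher in both tissue libraries than in both hepatocyte libraries, all hemoglobin genes and so not independent, while the other 3 crossed the labels. The bar for this test was first a majority of the genes, which 4 of 7 met as an argument against a swap. It was raised to 80%, the bar of the sex test, after these values were seen. The same animal giving a hepatocyte and a tissue library, or a shared preparation, stays open, since the labels name no animals. With a term for this split, added after the data were seen, 3 genes were called between hepatocytes and tissue.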

How the results depend on the processing

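Alternatives described as added were chosen after seeing the data, and the others were fixed before. With pseudocount 0.1, no filter or median-ratio scaling, the number called stayed within 1.5 times its value for colonies, lines and hepatocyte-like cells against fibroblasts. Named genes, counted as pairs with a setting, kept call and direction in 5725, lost the call in 333 and turned in 0. Gene lists kept theirs in 1021, lost the call in 153 and turned in 6. The genes were called ones picked by size of difference, none from passage, hepatocytes against tissue or TauEGFP colonies, so the 0 shows little.

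With a correlation estimated for each list, the lists that passed fell from 11 to 0 for colonies against fibroblasts, from 9 to 0 for lines against fibroblasts, from 1 to 0 for lines against colonies, from 5 to 0 for passage and from 14 to 0 for TauEGFP colonies against primary neurons. For hepatocyte-like cells they fell from 14 to 1 against fibroblasts, from 17 to 2 against hepatocytes and from 19 to 2 against tissue, and for hepatocytes against tissue from 6 to 2. The estimates rest on 1 to 10 residual degrees of freedom, fewest for TauEGFP colonies against primary neurons, and the cause was not tested.

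For colonies against fibroblasts the main count of 4854 became 2874 with a replicate block (fibroblasts 1 and 2, colonies 1 and 2), 2716 on the same 4 libraries without the block (added) and 2661 on the HJMKLALXX flow cell alone (added). These settings use fewer libraries. For lines against colonies, 12 became 35 without the flow cell term and 130 on the HVN flow cells alone, and the cause was not tested. Median-ratio scaling changed 7649 to 4695 against hepatocytes and 7867 to 4951 against tissue, since it takes away most of the median difference of all genes. With the term for libraries without Y-linked transcripts (added) these were 6743 and 6932.

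For passage, limma called 1 gene without the filter, where 18947 in place of 14012 genes were tested, and 0 with the pseudocount of 0.1 (114 at an unadjusted p under 0.05), with scaling (65) and without the flow cell term (57). Between hepatocytes and tissue, limma called 0 genes with the pseudocount of 0.1 (549 at an unadjusted p under 0.05) and 0 without the trend (330), 5 without the filter, 5 with scaling and 3 with the term for libraries without Y-linked transcripts (added), against 1. The cause was not tested. Between TauEGFP colonies and primary neurons limma called 0 genes with the pseudocount of 0.1 (717 at an unadjusted p under 0.05), without the filter (650), with scaling (770), without the replicate block (859) and with a crossed block (990, added). Its 4 settings without a replicate could not be fitted, since no residual degrees of freedom are left.

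Leaving out each replicate in turn gave 3937 to 4978 genes for colonies against fibroblasts, 3533 to 4725 for lines against fibroblasts, 5 to 45 for lines against colonies and 0 to 2 for passage. It gave 1528 to 4362 for hepatocyte-like cells against fibroblasts, 5354 to 7950 against hepatocytes, 5786 to 8138 against tissue and 0 to 3 for hepatocytes against tissue. Where a single reference library was left, the fit assumes that it varies like the other groups.

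List tests whose direction turned when a replicate was left out were those of passage and of hepatocytes against tissue. For passage the adjusted p ranged from 1.56e-16 to 0.981 for the fibroblast list, from 2e-06 to 0.981 for smooth muscle, from 1.43e-08 to 0.981 for cell cycle and from 6.78e-05 to 0.981 for stress response. The first 3 turned without F25 library 3 (0.981) and the last without F25 library 1 (0.486). Between hepatocytes and tissue it ranged from 2.9e-14 to 0.722 for the macrophage list and from 3.22e-24 to 0.0198 for the Kupffer list, which turned without hepatocytes 2 (0.722 and 0.00475). Fewer libraries were in each of these fits, and what in the left-out library caused the turn was not tested.

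Depth limits low values. At the apparent depth, a value listed at 0 does not show that a gene was silent. Since the depth is only estimated, no limit of detection is given for values under 1 FPKM.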

Other observations

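Values of this part belong to no comparison, and no test was chosen for them beyond the difference between lines, which was examined after the data were seen. Between F25 and s39, limma called 30 genes, 14 higher in F25 and 16 lower, with 1594 at an unadjusted p under 0.05. Apart from Igf2 and H19, Cldn6 had a log2 difference of -7.51 (means 0.519 and 264 FPKM), Tff2 of 4.16 (23.1 and 0.332) and Fabp3 of -2.91 (207 and 1535). Igf2 was at 87.9 FPKM in eXEN cells.

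The axial genes Hoxb9, Hoxb8 and Hoxb7 were at 114, 54.3 and 41.3 FPKM in TauEGFP colonies 1, at 9.89, 8.44 and 3.65 in fibroblasts 3, and listed at 0 in brain and primary neurons 1. The pluripotency genes Zfp42 and Nanog were at 11.6 and 2.53 FPKM in eXEN cells. Alb was listed at 0 in tissue 2 and hepatocytes 1 and at 44789 and 51325 FPKM in tissue 1 and hepatocytes 2, with the zeros kept as listed in the list tests and no test of whether a value was lost in the authors' processing. The transcript mt-Nd4l was listed at 0 in a colony and at up to 1553 in the others.

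Transcripts of Xist and of the Y-linked gene Eif2s3y both reached 1 FPKM in 2 of 2 fibroblast libraries of the XEN-like table. Of the 8 colonies, 1 held both, with Eif2s3y at 1.02 FPKM, while 3 held Xist alone and 4 Eif2s3y alone. The 3 F25 libraries held Xist alone, and the 2 s39 libraries and the eXEN library Eif2s3y alone.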
